A study of Saccharomyces cerevisiae with 6 samples.

How the data were processed

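RNA was measured in 6 cultures of the budding yeast Saccharomyces cerevisiae, 3 treated for 60 minutes with 20 uM edelfosine and 3 with the vehicle, 0.095% ethanol. Per the labels' protocols, RNA was extracted with hot acid phenol, poly(A) RNA was selected and libraries were made with an Illumina kit. Replicates 1 and 2 of each treatment were strain W303 and replicate 3 was strain BY4741, so the strain coincided with replicate 3 and cannot be told from the day or batch of that replicate. The labels call the replicates biological. Groups, strains and replicate numbers were taken from the labels.

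The authors deposited 1 table with a row per gene and a column per library. Its name speaks of read counts, but every column has the same total and the values are not whole, so the deposited values were treated as TPM, a unit of transcript abundance with a fixed total. The submitters' processing notes name kallisto and sleuth, without versions; the transcript set and genome build are not given in the sources used here. TPM keeps no depth, so the depth of each library is unknown and no counting interval or detection floor can be given. Of the 5917 rows, 5911 matched a locus tag of the R64 reference annotation, which served for gene names, neighbours and distance to the chromosome end. Coding lengths came from the same annotation. In total 38 rows in 16 groups held values identical to those of another row in every library, as for near-identical copies such as CUP1-1 and CUP1-2, so single members of such families are uncertain.

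A count model had been planned before the data were examined, together with a list of alternatives, 47 gene lists and the rule for named genes. Because the values were TPM, that quasi-likelihood count test and both alternative count tests that had been listed were not run. The test used instead, its pseudocount, its filter in TPM and the code for the planned TMM scaling were settled after the table had been seen. Before the final scaling was coded, unscaled TPM and a 30% trimmed mean of log2 deviations had already been fitted with 3 designs. These gave 2837 higher and 760 lower genes without scaling and 1688 higher and 1452 lower genes with the trimmed mean, under the design used here. In all 5 scalings were tried and all are reported.

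Rows with at least 1 TPM in at least 3 libraries were kept, which left 5707. Libraries were scaled by an unweighted trimmed mean of M values (TMM; 30% of M values and 5% of A values trimmed at each end), with factors from 0.715 to 1.25. The factors of the 3 edelfosine libraries were all above those of the 3 vehicle libraries. Changes were fitted on log2(scaled TPM + 1) with limma 3.58.1 in R 4.3.3 (empirical Bayes with a mean-variance trend), with strain and treatment as terms, 3 residual and 3.41 prior degrees of freedom, and Benjamini-Hochberg adjustment. An adjusted p under 0.05 was called, and every adjusted p for a gene below comes from this limma fit. Fold changes on this scale understate the change of low genes. The strain effect came from the same fit and the strain by treatment interaction from a fit with 2 residual degrees of freedom. The scaling sets the median gene near 0 (0.0087), whereas TPM as deposited rose by 0.55 at the median gene, so each change is relative to the median gene and not a change in RNA per cell.

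Gene lists were tested with limma's camera at a preset inter-gene correlation of 0.01, adjusted over the 46 lists with at least 3 tested members. Camera with an estimated correlation, which rests on only the 3 residual degrees of freedom, and the rotation test fry were the alternatives. The list of mitochondrially encoded genes had too few tested members. Subtelomeric genes were those within 20 kb of a chromosome end in R64. On data simulated for the treatment comparison over 5707 genes, with 200 changed, the fit recovered 77.6% of genes changed by 1 on the log2 scale, 97.0% of those changed by 2 and 100% of those changed by 4. Of its calls, 7.11% were not among the changed genes. The simulated changes had random signs and independent noise for each gene. These rates therefore do not cover scaling under a change as broad as that seen here, or correlated genes.

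Genes were named by a rule: the 12 largest rises and 12 largest falls among called genes with a symbol, the same direction in all 3 same-numbered pairs and a mean of at least 10 scaled TPM in the higher group (the rule had said CPM); up to 4 members with the smallest adjusted p of each list described; strain marker and mating-type genes; SIR2, SIR3, SIR4, LEM3, DNF1, DNF2, PMA1, INO1 and PDR5; and the 5 largest rises and falls between strains. Any other gene is marked as chosen after its values were seen. Alternatives covered scaling, filters, pseudocounts, designs, left-out libraries, multi-copy families, a fold threshold of 1.5, length and GC trends and the set test. The multi-copy alternative removed 386 tested genes by name pattern, among them the cytosolic ribosomal proteins and some unnamed reading frames.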

Results

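The series asked how a lysophosphatidylcholine analogue changes yeast gene expression. Edelfosine, a synthetic ether lipid of that kind, was given to log-phase cultures for 60 minutes and compared with its ethanol vehicle. There were 3 libraries per treatment, 2 of the common laboratory strain W303 and 1 of BY4741. Each library's TPM had the same total, and between 5550 and 5717 genes reached 1 TPM. Read depth is unknown. The strain labels were checked on auxotrophic marker genes, of which MET17, LEU2 and URA3 parted the strains by their near absence from BY4741 and HIS3 did not. MET17 was listed at 0 in both BY4741 libraries and at 32.9 to 55.7 TPM in the 4 W303 libraries. LEU2 lay at 0.0386 and 0.0868 TPM in BY4741 and at 101 to 278 TPM in W303, and URA3 at 0 and 0.0629 against 90.01 to 109 TPM. HIS3 lay at 90.5 and 102 TPM in BY4741 and at 24.3 to 52.7 TPM in W303. The a-factor gene MFA1 lay between 703 and 3751 TPM in every library, and the alpha-factor gene MF(ALPHA)1 stayed at or below 3.02 TPM.

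Edelfosine was followed by a broad change in the transcriptome, led by a rise of stress protectants and a fall of the protein synthesis machinery. The largest rise was that of SIP18 (YMR175W), a phospholipid-binding hydrophilin, from 19.4 ± 8.80 to 17540 ± 2082 scaled TPM (mean ± SD, n = 3 each). The log2 change was 9.83 with a standard error of 0.34. The small heat shock genes HSP26 (YBR072W) and HSP12 (YFL014W) rose by 8.33 ± 0.25 and 7.30 ± 0.34 (log2 ± SE). HSP12 reached 56637 ± 8193 scaled TPM. The hydrophilin gene GRE1 (7.17), the aldehyde dehydrogenase gene ALD3 (6.93), the proteinase inhibitor gene PAI3 (6.88), SPG4 (6.76), FMP16 (5.87) and SPG1 (5.85) were among the 12 largest rises. So were NQM1 (6.90), TKL2 (6.86) and GND2 (6.53), all enzymes of the pentose phosphate pathway. Adjusted p for these 12 genes lay between 2.04e-05 and 0.000643 in the limma fit.

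The largest falls were those of SAM1 (YLR180W; -4.63 ± 0.56) and DBP2 (YNL112W; -4.48 ± 0.50), which encode an S-adenosylmethionine synthetase and an RNA helicase. SAM1 went from 120 ± 8.45 to 4.97 ± 4.18 scaled TPM. Its paralogue SAM2 fell by 3.57. The ribosomal protein genes RPL9A (-4.27) and RPS26B (-3.65), the ribosome assembly genes NOP7 (-3.63) and NIP7 (-3.52), and IMD2 (-3.59), for guanine nucleotide synthesis, also fell. So did the zinc transporter gene ZRT1 (-4.11), the cell wall gene UTR2 (-4.07), the a-factor gene MFA2 (-3.68) and the ammonium permease gene MEP2 (-3.52). Values of SAM1, SAM2, RPL9A, RPS26B and IMD2 are uncertain because near-identical copies can share reads. Adjusted p for these 12 genes lay between 0.000231 and 0.00476 in the limma fit.

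**Figure D1:**
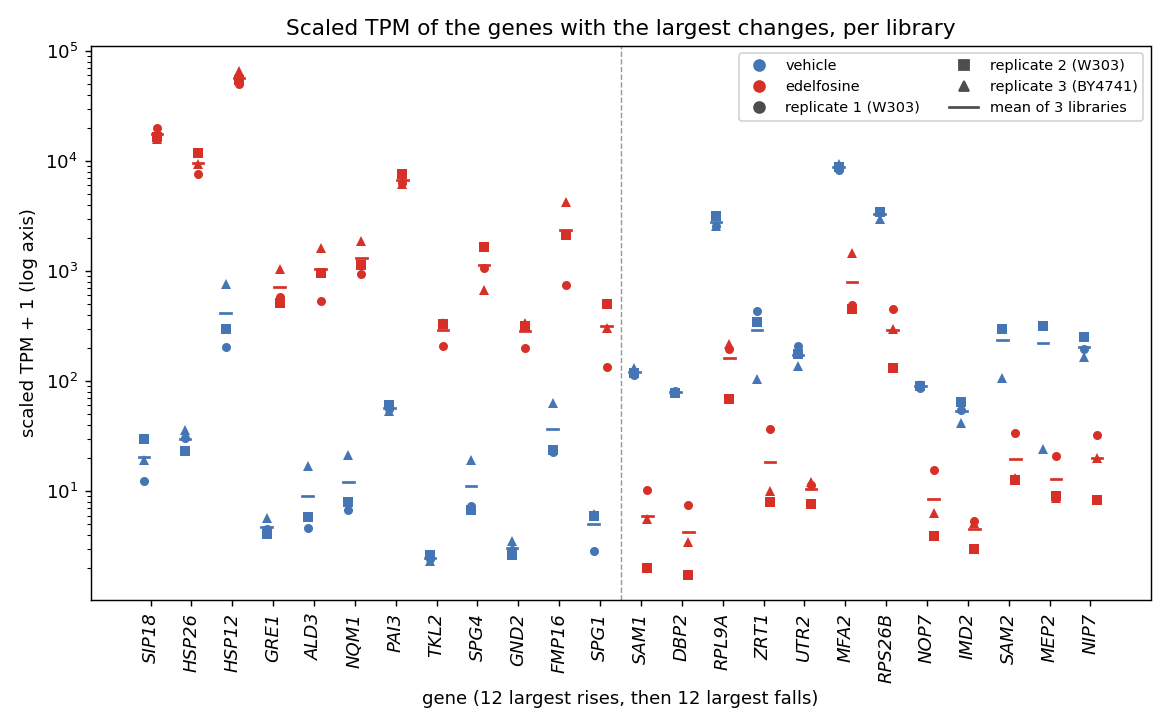
Scaled TPM plus the pseudocount of 1, on a log axis, for the 12 largest rises and 12 largest falls; points are single libraries, with shapes for replicates and colours for treatments, and bars are means of 3. The edelfosine libraries of SIP18 lie between 16005 and 19910 scaled TPM and the vehicle libraries between 11.4 and 28.9.

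Of 5707 genes tested, 3115 changed in the limma fit, 1557 higher and 1558 lower, and 3110 of them had the same direction in all 3 same-numbered pairs. Changes of 2-fold or more were seen for 807 higher and 910 lower genes. With TPM as deposited the split was 2837 higher and 760 lower, or 78.9% higher against 49.98% after scaling, so the balance of rises and falls is set by the scaling. Without replicate 2 of both treatments 1960 genes were called, and 1317 passed when the change was tested against 1.5-fold.

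Genes for making ribosomes fell almost as a block. Of 138 cytosolic ribosomal protein genes, 137 fell (median log2 change -2.54; adjusted p = 6.72e-29 by camera at the preset correlation, adjusted p = 0.456 with an estimated correlation). Their share of all TPM went from 53.0 ± 1.63% to 14.8 ± 3.74% (n = 3 each). RPS25B (-2.50), RPL1A (-2.71) and RPL22A (-2.56) had small adjusted p, and many of these genes are near-identical duplicates. The exception, chosen after its values were seen, was RPL15B, which rose by 0.65 ± 0.19 (adjusted p = 0.0274, limma). Of 74 ribosome biogenesis genes 72 fell (median -2.26; adjusted p = 9.93e-16, adjusted p = 0.492 with an estimated correlation), among them RRP1 (-2.58), ENP2 (-2.40) and NOP13 (-2.83). Both counts were the same when adjusted over the list alone.

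The 5 lists of general stress, oxidative stress, heat shock, proteasome and autophagy genes passed as rising. Of 34 targets of the general stress factors Msn2 and Msn4, 32 rose (33 adjusted over the list alone), with a median of 2.88, and their share of TPM went from 0.258 ± 0.150% to 11.0 ± 1.85% (adjusted p = 1.34e-12, adjusted p = 0.456 with an estimated correlation). The chaperone gene SSA4 rose by 4.75. In the oxidative stress list 13 of 19 genes rose and 1 fell (adjusted p = 0.000399; adjusted p = 0.456 with an estimated correlation), led by the peroxiredoxin genes PRX1 (3.69) and TSA2 (4.42) and by TRX3 (2.46) and GTT2 (1.60). The fall, named after its values were seen, was that of OYE2 (-1.55). Heat shock genes of the Hsf1 list rose in 8 of 20 cases and fell in 1 (adjusted p = 0.0491; adjusted p = 0.658 with an estimated correlation), with HSP82 at 2.36, SSA1 at 2.83 and HSP60 at 1.76. This list's call was also lost in several other settings, among them the fits without vehicle replicate 1 (adjusted p = 0.0845), vehicle replicate 3 (0.0521), edelfosine replicate 2 (0.0913) and edelfosine replicate 3 (0.0522). Proteasome genes rose in 27 of 33 cases, by a median of 0.61 (adjusted p = 8.46e-06; adjusted p = 0.456 with an estimated correlation), including RPN6 (1.05) and SCL1 (1.20). In the autophagy list 17 of 22 genes rose (adjusted p = 0.000249; adjusted p = 0.456 with an estimated correlation), ATG8 by 2.30 and ATG33 by 2.18, while ATG41 fell by 2.28.

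Mitochondrial and alternative carbon genes rose as well. Of 70 mitochondrial ribosomal protein genes 62 rose (66 adjusted over the list alone; median 0.87), such as IMG1 (1.80) and MRPS12 (1.44), with adjusted p = 3.78e-12 and adjusted p = 0.456 with an estimated correlation. In the list of the citric acid cycle and respiratory chain 31 of 46 rose (33 adjusted over the list alone), including LSC2 (2.16), KGD2 (1.66) and MDH1 (2.02). That list had adjusted p = 8.50e-06 and adjusted p = 0.470 with an estimated correlation. Its 1 fall was CYC1, a cytochrome c gene (-1.92), named after its values were seen. Gluconeogenic and glucose-repressed genes rose in 20 of 26 cases (21 adjusted over the list alone), with the hexose kinase genes HXK1 (4.50) and GLK1 (2.63) and the peroxisomal thiolase gene POT1 (4.38) in front (adjusted p = 9.54e-06; adjusted p = 0.456 with an estimated correlation). The 1 fall, named after its values were seen, was that of ADH2 (-1.01). Glycolysis and fermentation genes fell in 11 of 21 cases and rose in 2 (adjusted p = 0.0203; adjusted p = 0.658 with an estimated correlation). ENO2 (-2.23) and TDH2 (-2.59) fell, while TDH1 rose by 1.19. By fry this list did not pass (adjusted p = 0.0927). The share of this list in deposited TPM was 2.91 ± 0.56% and 2.81 ± 0.54%.

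Among the lipid lists, the regulon of Ino2, Ino4 and Opi1 for phospholipid synthesis fell in 13 of 18 genes and rose in 0 (median -1.76; adjusted p = 7.23e-05, adjusted p = 0.456 with an estimated correlation). Falls were seen for CHO1 (-3.09), which encodes phosphatidylserine synthase, the choline transporter gene HNM1 (-2.24), PSD1 (-2.02) and CPT1 (-1.76). INO1, for inositol synthesis, fell by 2.84 ± 0.54 (adjusted p = 0.00553, limma). Neutral lipid and fatty acid genes rose in 9 of 18 cases and fell in 1 (adjusted p = 0.0323; adjusted p = 0.456 with an estimated correlation). The fatty acid desaturase gene OLE1 rose by 3.65 and its activator gene MGA2 by 2.51, and FAA3 fell by 0.98, which did not pass with TPM as deposited. The list's call was lost without vehicle replicate 2 (adjusted p = 0.0514) and without the strain term (0.0714). Sphingolipid genes went both ways, 7 up and 10 down of 32, and the list did not pass (adjusted p = 0.545, camera), its median turning from -0.19 to 0.35 with TPM as deposited. The elongase genes ELO2 (-2.54) and ELO3 (-2.74) fell and the kinase gene YPK2 rose (1.43). Ergosterol synthesis genes had 2 rises and 2 falls among 26 (1 and 1 adjusted over the list alone; adjusted p = 0.933, camera). HMG2 changed by 1.05, ERG3 by 1.00, ERG2 by -1.08 and ERG4 by -0.63. The calls of ERG3 and ERG4 were lost without vehicle replicate 1 (adjusted p = 0.0662 and 0.0706, limma) or vehicle replicate 2 (0.121 and 0.0771), and that of ERG3 also without vehicle or edelfosine replicate 3 (0.138 for each) and with the GC trend removed (0.0626). With TPM as deposited ERG4 was at -0.03 (adjusted p = 0.881, limma), and without the strain term its call was lost too (0.176). In the list of lysophospholipid uptake and turnover 3 of 18 rose, SPO1, GDE1 and PLB2, by 1.00, 1.01 and 1.14 (list adjusted p = 0.226, camera). The flippase genes LEM3, DNF1 and DNF2, which carry such lipids inward, had log2 changes of 0.23 ± 0.13, 0.18 ± 0.15 and -0.28 ± 0.13 (adjusted p = 0.188, 0.350 and 0.117, limma). With TPM as deposited, where the median gene itself shifted by 0.55, LEM3 and DNF1 were called higher, at 0.81 and 0.66. DNF2 turned to 0.15 without passing.

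Membrane and transport genes changed in both directions. Pleiotropic drug resistance genes rose in 12 of 20 cases (13 adjusted over the list alone) and fell in 3 (adjusted p = 0.0180; adjusted p = 0.456 with an estimated correlation). The efflux pump gene PDR5 rose by 1.56 ± 0.22 (adjusted p = 0.00197, limma), RSB1 by 1.53, RTA1 by 1.26 and the proteasome activator gene RPN4 by 1.94, while ATR1 fell by 2.48. With TPM as deposited the list did not pass (adjusted p = 0.116). Proton pump genes fell in 13 of 19 cases (adjusted p = 0.00736; adjusted p = 0.456 with an estimated correlation), with the vacuolar subunits VMA16, VMA5, VPH1 and VMA11 at -0.94, -0.88, -0.96 and -1.09; the first 3 did not pass with TPM as deposited. Their share of deposited TPM was 1.40 ± 0.10% and 1.39 ± 0.44%. The plasma membrane ATPase gene PMA1 fell by 1.60 ± 0.47 (adjusted p = 0.0271, limma). That call was lost with TPM as deposited (-0.99; adjusted p = 0.0904) and without vehicle replicate 1, 2 or 3 or edelfosine replicate 3 (0.0808 to 0.106). Endocytosis and ubiquitin ligase genes rose in 13 of 25 cases, with UBI4 at 1.74 and ABP1 at 1.51 (adjusted p = 0.00642; adjusted p = 0.521 with an estimated correlation). Eisosome genes rose in 5 and fell in 2 of 15 cases (adjusted p = 0.199, camera), PKH1 by 1.46, and SUR7 fell by 2.31. The list passed without edelfosine replicate 1 (adjusted p = 0.0261), and the call of SUR7 was lost without vehicle replicate 1 or 2 (0.0691 and 0.0694, limma). Cell wall integrity genes rose in 11 and fell in 5 of 25 cases without passing (12 and 6 adjusted over the list alone; adjusted p = 0.218, camera). PIR3 rose by 4.40, SPI1 by 3.63 and PST1 by 3.12.

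Of 6 lists of nutrient regulons, 3 passed, and these pointed down. Amino acid synthesis genes under Gcn4 fell in 34 of 43 cases (40 adjusted over the list alone, with 1 rise), with LYS20 at -2.83, HIS4 at -2.18 and ARO2 at -1.99 (adjusted p = 2.50e-11; adjusted p = 0.456 with an estimated correlation). Sulfur and methionine genes fell in 12 of 25 cases and rose in 2, with MUP1 at -1.92 and MMP1 at 1.28 (adjusted p = 0.0323; adjusted p = 0.456 with an estimated correlation). That call was lost without edelfosine replicate 1 (adjusted p = 0.0796) and without the strain term (0.0585). The phosphate regulon fell in 12 of 18 cases (13 adjusted over the list alone) and rose in 2, with SPL2 at -3.23 and PHO3 at -3.32 (adjusted p = 0.0118; adjusted p = 0.521 with an estimated correlation). In deposited TPM this regulon's share was 0.0666 ± 0.0166% and 0.0813 ± 0.0259%. The nitrogen list had 8 rises and 7 falls of 24, with a median of 0.18, a mean of -0.16 and a set test pointing up (adjusted p = 0.788, camera). CIT2 fell by 2.42 and UGA1 rose by 1.65. The zinc and copper list had 6 rises and 6 falls of 16, with IZH4 at 4.92 and ADH4 at -1.37. Its median and camera pointed down and fry pointed up (adjusted p = 0.958, camera). The iron regulon had 3 rises and 8 falls of 22 (adjusted p = 0.185, camera), with LSO1 at 3.68 and FTR1 at -2.10, and passed without edelfosine replicate 1 (adjusted p = 0.0223). The medians of the zinc and copper list and of the iron list turned to 0.28 and 0.29 with TPM as deposited.

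The lists of core histones, G1 genes, the CLB2 cluster, the nuclear envelope and MATa-specific genes passed, and all 5 pointed down. Core histone genes fell in 9 of 10 cases, with HTA2 at -3.29 and HTB2 at -3.16 (adjusted p = 0.000249; adjusted p = 0.456 with an estimated correlation). G1 genes of SBF and MBF fell in 9 of 20 cases and rose in 1, with TOS4 at -2.32 and GIC2 at -2.28 (adjusted p = 0.00782; adjusted p = 0.456 with an estimated correlation); their median turned from -0.45 to 0.050 with TPM as deposited, and the call was lost with at least 10 TPM in 3 libraries (adjusted p = 0.0781). The CLB2 cluster fell in 5 of 15 cases, with CLB1 at -1.86 and CDC5 at -1.36 (adjusted p = 0.0207; adjusted p = 0.658 with an estimated correlation). That list's call was lost without vehicle replicate 1 (adjusted p = 0.0566), without edelfosine replicate 1 (0.156), with at least 10 TPM in 3 libraries (0.230) and by fry (0.217). Without replicate 2 of both treatments the calls of CLB1 and CDC5 were lost (adjusted p = 0.0571 and 0.0643, limma). Nuclear envelope and pore genes fell in 16 of 37 cases (14 adjusted over the list alone) and rose in 1, with APQ12 at -1.41 and NUP100 at -1.06 (adjusted p = 0.00694; adjusted p = 0.456 with an estimated correlation). With TPM as deposited this list did not pass (adjusted p = 0.277) and its median turned from -0.40 to 0.15, NUP100 did not pass (0.0553, limma), and the list's call was also lost with at least 10 TPM in 3 libraries (0.109). MATa-specific genes fell in 6 of 7 cases, with the pheromone receptor gene STE2 at -3.08, BAR1 at -2.45, STE6 at -2.15, MFA1 at -1.97 and AGA2 at -0.97 (adjusted p = 0.00387; adjusted p = 0.456 with an estimated correlation). ASG7 had a change of 0.65 ± 0.32 (adjusted p = 0.131, limma) and was called higher without edelfosine replicate 1 (1.03; adjusted p = 0.00185). The call of AGA2 was lost with TPM as deposited (-0.38; adjusted p = 0.219, limma) and without vehicle replicate 1 or 2 (0.0785 and 0.0669). None of the 4 tested MATalpha-specific genes was called, with AFB1 at 0.35, MF(ALPHA)2 at 0.46, STE3 at 0.29 and SAG1 at -0.05 (list adjusted p = 0.404, camera). With TPM as deposited, where the median gene itself shifted by 0.55, ASG7, AFB1, MF(ALPHA)2 and STE3 were called higher, at 1.20, 0.88, 1.00 and 0.63. MF(ALPHA)2 was also called higher without edelfosine replicate 1 (0.61).

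Other lists did not pass the set test. The pheromone response list had 1 rise and 6 falls of 14 (adjusted p = 0.148, camera), with FAR1 at -1.40. Meiotic genes, markers of sporulating diploids, had 8 rises and 2 falls of 15 (9 and 3 adjusted over the list alone; adjusted p = 0.0727, camera), DMC1 at 2.23 and SPS4 at -1.64. The M/G1 list had 1 rise and 4 falls of 14 (0 and 4 adjusted over the list alone; adjusted p = 0.202, camera) and passed without vehicle or edelfosine replicate 3 (0.0197 and 0.0194). The medians of the pheromone and M/G1 lists turned to 0.21 and 0.18 with TPM as deposited. DNA damage genes had 6 rises and 2 falls of 17 (adjusted p = 0.396, camera), with RNR1 at -2.28 and MAG1 at 2.23. The calcineurin list had 6 rises and 3 falls of 17 (adjusted p = 0.427, camera), with RCN1 at 1.40. Genes of the unfolded protein response had 7 rises and 2 falls of 21 (adjusted p = 0.350, camera), with PDI1 at 0.99. The Rim101 list had 6 rises and 2 falls of 13 (adjusted p = 0.275, camera), with RIM8 at 1.63. The sterol uptake and anaerobic list had 5 rises and 2 falls of 13 (adjusted p = 0.577, camera), with ANB1 at -1.91. The strain marker loci had 1 rise and 1 fall of 9 (adjusted p = 0.396, camera), with SSD1 at 0.91 and LYS2 at -1.77. Without replicate 2 of both treatments SSD1 did not pass (adjusted p = 0.0510, limma).

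In all, 27 of 46 lists passed at the preset correlation, 14 up and 13 down. With an estimated correlation 0 passed, and fry, which does not compare a list with other genes, called 32. The estimated version rests on 3 residual degrees of freedom, which limits what it can call. Core histones and nuclear envelope genes had estimated correlations of -0.071 and -0.0022, both under the preset 0.01. Their camera adjusted p still went from 0.000249 and 0.00694 to 0.456 for each. The loss of calls therefore cannot be put down to correlation between genes alone. Of the lists that camera did not call, fry called cell wall integrity (adjusted p = 0.00756), silent chromatin and telomere factors (0.00808), meiosis (0.0193), sphingolipid metabolism (0.0250), pheromone response (0.0250), MATalpha-specific genes (0.0352) and lysophospholipid uptake and turnover (0.0396). It did not call glycolysis (0.0927) or the CLB2 cluster (0.217), which camera called. Another split of the 6 libraries, which mixed the treatments, called 28 lists.

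**Figure D2:**
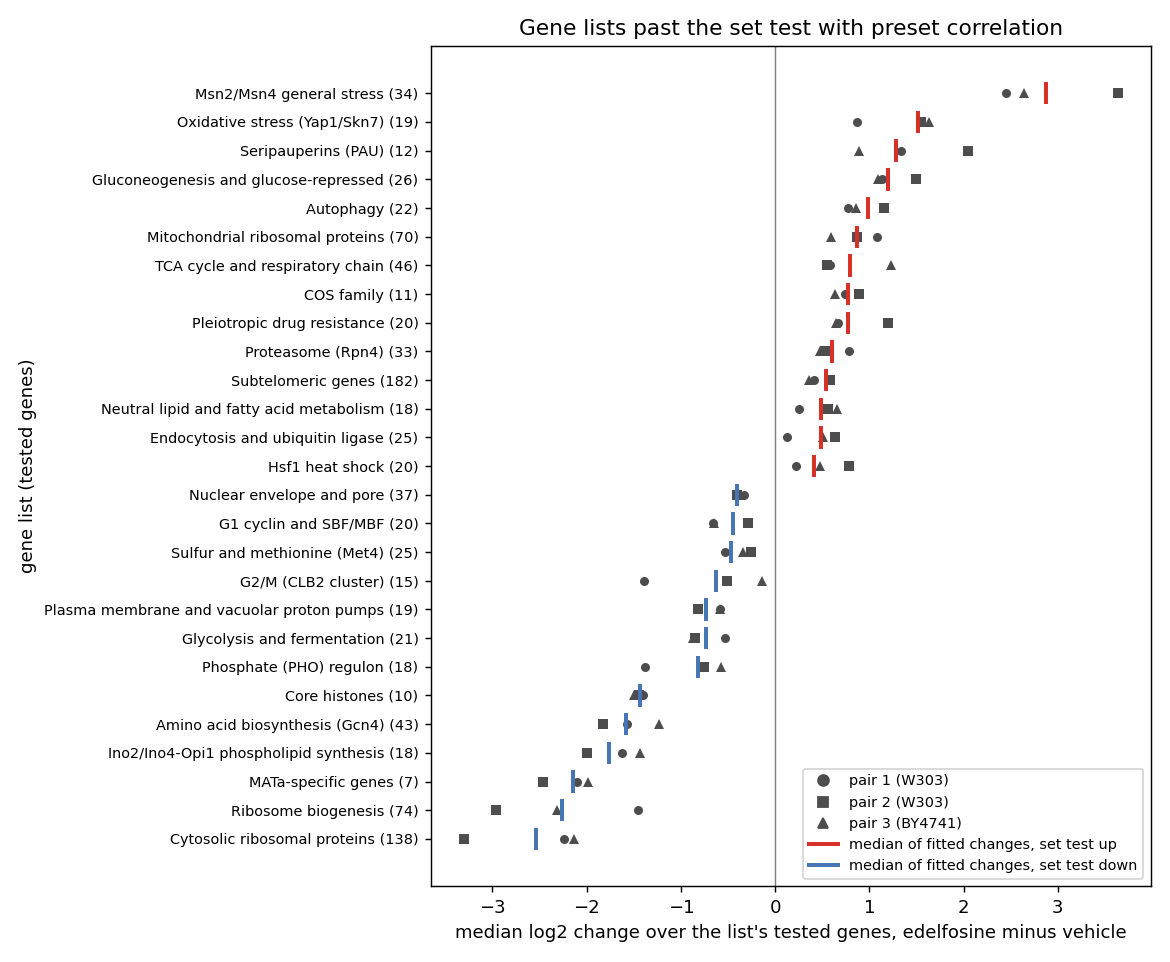
Median log2 change (edelfosine minus vehicle, on scaled TPM) over the tested genes of the 27 lists past the set test at the preset correlation; symbols are the 3 same-numbered pairs and bars the median of the fitted changes. The Msn2/Msn4 list lies at 2.88 and the cytosolic ribosomal proteins at -2.54.

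Among tested genes, those near chromosome ends rose more often than others. Of 239 rows within 20 kb of an end, 182 passed the filter and were tested. Of these 182 genes, 82 rose (45.1% against 26.7% of other genes) and 24 fell (13.2% against 27.8%). Their median change exceeded that of other genes by 0.54 (adjusted p = 0.000896, camera; adjusted p = 0.456 with an estimated correlation). The enolase-related genes ERR1 and ERR2, which held identical values, rose by 3.97, HSP33 by 4.35 and the glutathione transferase gene GTT1 by 3.85. The first 3 have near-identical copies and are uncertain. The COS family rose in 9 of 11 cases, COS10 by 1.54 (camera adjusted p = 0.00277, and 0.456 with an estimated correlation). Of 24 seripauperins only 12 passed the filter. Of these 8 rose (10 adjusted over the list alone) and 1 fell, with PAU2 at 1.78. Camera gave that list adjusted p = 0.00799, and 0.499 with an estimated correlation. It gave 0.0847 with TPM as deposited and 0.129 with at least 10 TPM in 3 libraries. COS genes and seripauperins are both multi-copy families. PAU21 and PAU22 held identical values, so 1 measurement counts as 2 members. They lay at 0.581 to 1.10 scaled TPM in vehicle and passed the filter only through the edelfosine libraries. Silencing and telomere factors had 2 rises and 7 falls of 26 without passing (adjusted p = 0.116, camera), with RIF1 at -0.83 and HTZ1 at -0.91, neither of which passed with TPM as deposited. SIR2, SIR3 and SIR4, for the silencing complex, had log2 changes of 0.12 ± 0.13, -0.28 ± 0.14 and -0.09 ± 0.13 (adjusted p = 0.463, 0.146 and 0.572, limma). With TPM as deposited, where the median gene itself shifted by 0.55, SIR2 was called higher at 0.62 and the signs of SIR3 and SIR4 turned. The difference of 0.54 was 0.29 without multi-copy families, 0.28 without the low-value filter and 0.27 with a pseudocount of 5. It was 0.20 over the 95 subtelomeric genes with at least 95% unique sequence words. A gene under 1 TPM in every vehicle library passed the filter only if it reached 1 TPM in all 3 edelfosine libraries. ERR1 and ERR2, at 0.321 to 0.562 scaled TPM in vehicle, entered in this way. The filter thus favours rises among low genes, and the difference of 0.54 holds that selection.

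**Figure D3:**
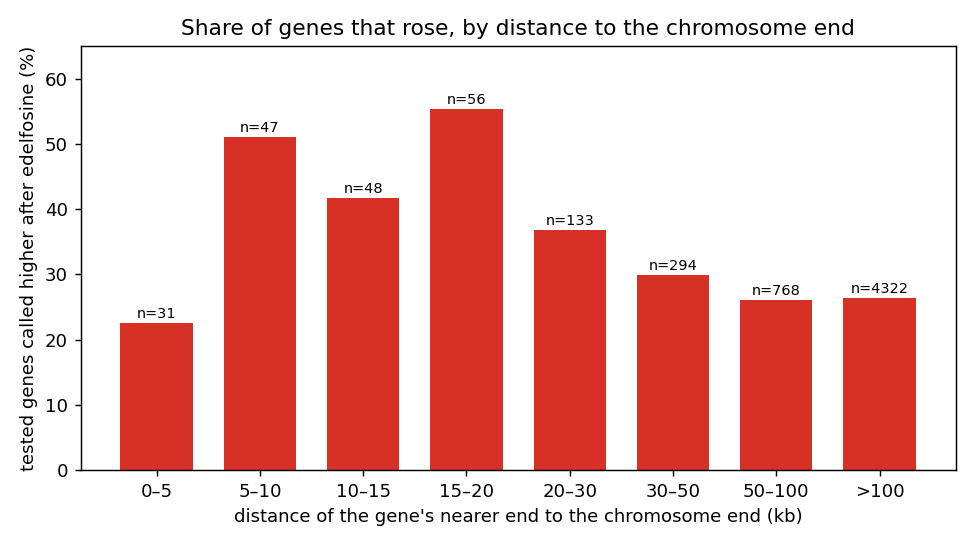
Percent of tested genes called higher after edelfosine, by the distance of the gene's nearer end to the chromosome end in the R64 annotation; numbers above the bars are genes. The share is 22.6% within 5 kb, 51.1% from 5 to 10 kb and 26.3% beyond 100 kb.

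Between strains, 24 genes differed in the limma fit, 9 higher and 15 lower in BY4741, and 658 had an unadjusted p under 0.05. Besides LEU2, URA3 and MET17, the lowest genes with a symbol were DAL80, at 20.2 scaled TPM in W303 and 0.716 in BY4741 (adjusted p = 0.00616, limma), and CYC1, at 389 and 50.03 (adjusted p = 0.00763, limma). QDR2, a drug transporter gene, stood at 9.59 in W303 and 47.2 in BY4741 (adjusted p = 0.0102, limma), TRP1 at 22.5 and 105, RIB4 at 323 and 1082, GAS2 at 0.961 and 4.03, and TIR1 at 0.636 and 3.11. The count rested on single libraries. It was 7, 1 and 1 without vehicle replicates 1, 2 and 3, and 87, 217 and 5 without edelfosine replicates 1, 2 and 3. The strain cannot be told from replicate 3.

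No gene passed the limma test of a strain-dependent response to edelfosine. The count was 0 of 5707, the smallest adjusted p was 0.982, and 176 genes had an unadjusted p under 0.05. With 1 BY4741 library per treatment, the spread came from W303 alone. Across genes, which are not independent replicates, the log2 changes of the BY4741 pair correlated with those of the W303 pairs at 0.85 and 0.93, and the W303 pairs with each other at 0.88.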

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

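Among the genes named for the treatment and the gene lists, a few values pointed one way in both W303 pairs and the other way in the BY4741 pair, which is 1 pair. The remaining tested genes were not searched for such opposite changes. For genes the difference was tested by the strain by treatment interaction in limma and did not pass. BY4741 exceeded the W303 mean change by 0.96 for URA3, which is near 0 TPM in BY4741, by 0.70 for TRP1 and by 0.32 for SAG1 (adjusted p = 1.00 for each). For lists the difference was not tested. The median of the M/G1 list was higher in BY4741 than the W303 mean by 0.97, that of the strain marker loci by 0.83 and that of ergosterol synthesis by 0.37. It differed by -0.45 for the unfolded protein response, by -0.35 for sterol uptake and anaerobic genes and by -0.25 for the calcineurin list. No test for single outlying libraries was run on groups of 3 libraries.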

How the results depend on the processing

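TPM as deposited, the trimmed-mean scaling, the pseudocounts of 0.1 and 5, the length and GC corrections and the fit without a mean-variance trend were chosen after the data had been seen. The planned count tests were not run on TPM. Over scalings, filters, pseudocounts and designs the number of changed genes stayed between 2450 (at least 10 TPM in 3 libraries) and 3597 (TPM as deposited). Larger moves were 1317 genes (611 higher, 706 lower) against a fold threshold of 1.5, a stricter question, and 2837 higher with 760 lower in TPM as deposited. Under the latter 2317 of the 3115 calls kept their direction and call and 139 turned direction. With an estimated correlation 0 lists passed and the subtelomeric difference of 0.54 had adjusted p = 0.456, against a range of 0.000467 to 0.0189 over the other alternatives. The strain count was 39 without a filter, where more genes were tested. Genes with a strain-dependent response numbered 0 with median-of-ratios and trimmed-mean scaling, TPM as deposited, no filter and both pseudocounts; upper-quartile scaling and the 10 TPM filter were not run for the strain results.

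Leaving out libraries gave 1960 to 3395 changed genes (941 to 1713 higher, 1019 to 1682 lower), the lowest without replicate 2 of both treatments, 25 to 27 lists, subtelomeric differences of 0.43 to 0.54 and 1 to 217 strain genes. Fewer libraries were then tested. Without vehicle replicates 1 and 2, 2199 and 2184 of the 3115 calls were kept, and 2975 without edelfosine replicate 1.

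Over all tested genes, 139 of the 3115 calls turned direction with TPM as deposited and 2 with the GC trend removed. The medians of the called G1 and nuclear envelope lists turned too in TPM as deposited, to 0.050 and 0.15, where all genes shifted by 0.55. Among the named genes and the list medians taken relative to all genes, those that turned sign are given here, and none was past the threshold in the reported fit or in a setting where its sign turned; the cause was not tested. With their sign kept, M/G1 passed without vehicle replicate 3, edelfosine replicate 3 or both (adjusted p = 0.0197, 0.0194 and 0.0196, camera), LEU2 without edelfosine replicate 1 (adjusted p = 0.0499, limma) and TRP1 with TPM as deposited (0.0171). In TPM as deposited the log2 changes of SAG1, LEU2, SIR3, SIR4 and DNF2 became 0.41, 0.0034, 0.23, 0.38 and 0.15, and the medians of the calcineurin and ergosterol lists, relative to all genes, 0.0083 and 0.016. The calcineurin median was 0.075 without a filter, 0.37 with at least 10 TPM, 0.076 with a pseudocount of 0.1, 0.0013 with the length trend removed and 0.049 with the GC trend removed. At 10 TPM the DNA damage median was -0.23. Without multi-copy genes the zinc and copper median was 0.042. With the GC trend removed SAG1 was 0.0023 and the nitrogen median -0.0087. Over left-out libraries SAG1 ranged from -0.16 to 0.020, LEU2 from -0.81 to 0.027, TRP1 from -0.083 to 0.34, and the medians of the calcineurin list from -0.055 to 0.13, ergosterol from -0.22 to 0.099, sterol uptake from -0.0068 to 0.21 and M/G1 from -0.76 to 0.020.

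The replicate block in place of strain gave 3017 changed genes, with 2956 of the 3115 calls kept, 27 lists and a subtelomeric difference of 0.54 (adjusted p = 0.000607, camera). Deviations of same-numbered libraries correlated at 0.33, 0.052 and 0.51 for replicates 1, 2 and 3, and 5 of 6 libraries correlated best with their own number. Replicate 3 is BY4741 in both treatments, so its correlation also holds the strain. Within W303 the difference between replicates 1 and 2 correlated at only 0.050 between vehicle and edelfosine, so the data gave little hint of pairing beyond the strain. Depth is unknown, so what it limits cannot be given.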

Other observations

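The lists and pairs in the next 2 paragraphs, and the tests of ribosomal protein rows, of gene length, of stress genes near chromosome ends and of both cell types, were chosen after the results had been seen. The other tests were set before their own outcome was known, although the difference without multi-copy families had been seen when the test of shared reads was set. More of the machinery of growth fell. All 18 aminoacyl-tRNA synthetase genes tested fell (median -1.61; THS1 at -2.01, ILS1 at -1.86), as did 31 of 34 translation factor genes with 1 rise (median -1.34; TIF1 at -2.24). RNA polymerase I and III subunit genes fell in 19 of 20 cases (RPA43 at -2.69, RPA190 at -2.46) and those of RNA polymerase II in 7 of 11. Purine and pyrimidine genes fell in 20 of 29 cases and rose in 2. Trehalose and glycogen genes rose in 13 of 19 cases and fell in 1, with PGM2 at 3.95, GPH1 at 3.66 and NTH1 at 2.29. These 6 lists passed camera at the preset correlation (adjusted p between 3.26e-08 and 0.0132) and none passed with an estimated correlation (0.459 to 0.464). Haploid-specific genes (0 rises, 5 falls of 11; adjusted p = 0.0567, camera), peroxisome biogenesis (7 and 2 of 26; 0.0689), the cytosolic chaperonin (0 and 4 of 8; 0.0634) and ubiquitin-conjugating enzymes (5 and 1 of 12; 0.191) did not pass.

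In 11 of 23 pairs of isozymes or other related genes the members were called in opposite directions. The pairs were written down when several of these values were known, so the count is a description and carries no test. GND2, TKL2, NQM1 and HXK1 had log2 changes of 6.53, 6.86, 6.90 and 4.50, and their partners GND1, TKL1, TAL1 (which was not called) and HXK2 of -1.63, -1.31, -0.12 and -1.59. ENO1 and ENO2 changed by 1.02 and -2.23, CIT1 and CIT2 by 1.48 and -2.42, and CYC7 and CYC1 by 2.44 and -1.92. Members of a pair that are similar in sequence can share reads, so the single values of such pairs are uncertain. In other pairs both members moved alike, as MDH1 (2.02) with MDH2 (1.97) and ANB1 (-1.91) with HYP2 (-0.64).

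The 3 results across genes were set against all 10 splits of the 6 libraries into 3 and 3, which are too few for a share under 0.05. Each split but the real one mixed treated and vehicle libraries, so the treatment entered both its contrast and its residual spread. Such splits are no reference for the absence of an effect. For changed genes 1 split of 10, the real one, reached 3115, and the highest other gave 0. For lists 2 splits of 10 reached the real 27, and the highest other, which set vehicle 1, vehicle 3 and edelfosine 3 against the rest, gave 28. For the subtelomeric difference 1 split of 10 reached the real 0.54, and the highest other gave 0.41.

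The rise of subtelomeric genes may rest in part on reads shared between copies. Over the 95 genes with at least 95% unique 31-mers the difference from other such genes was 0.20, under the bound of 0.27 set beforehand for this explanation. Its p of 0.0385, by camera at the preset correlation, was not adjusted over the lists, and no estimated correlation was run for it. The 87 other subtelomeric genes had a median change of 0.67. Elsewhere 256 genes had such low uniqueness, with a median of -0.48, and the 178 of them that were not ribosomal protein genes had a median of -0.06. Low expression was argued against, since the subtelomeric median lay at percentile 100 of 10000 random lists matched on mean expression, whose median was 0.043. The listed stress and glucose-repressed genes were argued against as the whole cause, since the difference was 0.43 over 117 genes in none of the other lists or families. Stress and glucose-repressed genes outside the lists could remain among the 117, so the test cannot exclude them. Genes with shared 31-mers were not taken out either. An effect of edelfosine on silencing stays open and untested, and the share of genes that rose was not highest nearest the ends.

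The median gene had a higher TPM after edelfosine, by 0.55 on the log2 scale, in a unit with a fixed total of which ribosomal protein mRNAs took a smaller share. With those rows left out and the rest rescaled the shift was -0.19. The known shares alone set a move of -0.86 for every other gene, before the pseudocount of 1, so this outcome was fixed beforehand. In a fixed total, the smaller ribosomal protein share leaves a larger share to all other rows together. Whether ribosomal protein mRNAs fell or other mRNAs rose per cell cannot be told from TPM. Gene length was argued against, since the shift lay between 0.46 and 0.71 in every decile of coding length, a range of 0.244 and only just under the bound of 0.25 set for that test. A change in total RNA per cell cannot be seen in TPM and was not tested.

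The fall of MATa-specific genes (median -2.15) was set against a change of cell type. Alpha cells were argued against, because the MATalpha-specific genes had a median change of 0.32 and MF(ALPHA)1 lay between 0.597 and 0.633 TPM after edelfosine. Diploid cells were argued against as the whole cause, because haploid-specific genes had a median change of -0.51, with STE18 at 0.25 and STE5 at 0.0096, although HO was at -3.16 and FAR1 at -1.40. A contribution of diploid or sporulating cells stays open, since the meiosis list had 8 rises of 15, a median of 0.48 with each of the 3 pairs above 0, and passed by fry (adjusted p = 0.0193) though not by camera (0.0727). That support is weak, because the filter favours rises among low genes. REC8 lay at 0.185 to 0.432 and SGA1 at 0.927 to 1.17 scaled TPM in vehicle, and both passed the filter only through the edelfosine libraries. An effect of the treatment on the MATa-specific genes stays open as a hypothesis.

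Long genes had lower TPM in every library, with slopes of log2 scaled TPM on log2 coding length between -1.13 and -1.04. The mitochondrially encoded Q0130 lay at 25.7, 44.3 and 43.3 TPM in vehicle and at 75.6, 90.8 and 44.5 TPM after edelfosine, in replicates 1, 2 and 3. None of the 4 genes of the 2-micron plasmid was called (adjusted p between 0.221 and 0.932, limma).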
